A study of Mus musculus with 2 samples.

How the data were processed

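Total RNA from gastrocnemius, the large muscle of the calf, was sequenced from 2 tissue samples of adult female mice aged 8 to 10 months. Per the labels, the mice came from a cross between 5xFAD, a transgenic line that carries mutated human transgenes, APP among them, and is used as a model of Alzheimer's disease, and CAST, a wild-derived inbred strain. The labels number the tissue samples as biological replicates 1 and 2, give each its own sample identifier and give both 1 donor identifier, so they do not settle whether the tissue came from separate animals. Per the labels, 300 ng of RNA went into each library, RNA was extracted with a column kit for animal tissue, libraries were made with a directional kit, and a mixture of ERCC spike-in RNAs for ribosomal-RNA-reduced libraries was added. Both libraries form 1 group, so there is no comparison between groups.

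The sources used here do not name the software that made the deposited tables. Per the deposited read-me, reads were assigned to the mm10 mouse genome with the GENCODE M21 annotation. Per the file headers, 1 gene table and 1 transcript table per library have the columns that RSEM writes, and these are called the first quantifier below. The other transcript table of each library has the columns that kallisto writes and is called the second quantifier. Per the deposited read-me, the first was made from an alignment to transcripts and the second straight from the reads. Expected counts in the deposited tables of the first quantifier and estimated counts in those of the second are not whole numbers, because reads that fit several genes or transcripts are shared among them. TPM, the share of a library's transcripts after correction for transcript length, was computed by the authors over all entries of a table, spike-ins included. The percent of a gene's TPM held by each transcript is also given by the authors in the deposited transcript table, and was recomputed here from TPM. Bounds of an interval of TPM in the deposited gene tables were not used here, because their level is not given in the sources used here.

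The gene tables list 55536 genes, 96 spike-ins and 26248 entries with a numeric identifier. The entries with a numeric identifier together held 1 expected count in library 1 and 0 in library 2 and were left out. All 55536 gene identifiers matched the GENCODE M21 annotation, which gave symbols, types and mm10 coordinates. The transcript tables list 141862 transcripts of these genes. Human APP is not among the annotated mouse genes, so the App values are those of the mouse gene entry. Reads from CAST alleles were assigned against the mm10 reference, and the effect of this on single genes was not tested. Where 2 identifiers share a symbol (Aldoa, Rmrp), the one with the higher TPM was used.

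Total expected counts were 35594289 in library 1 and 34541905 in library 2, of which spike-ins held 0.479% and 0.504%. A gene with no count could still be present at up to 3 counts, which is 0.0847 CPM (counts relative to the library total) in library 1 and 0.0873 CPM in library 2. Intervals and floors cover counting error only. With 2 libraries, each mean ± SD has 1 degree of freedom, and an exact two-sided sign-flip test could not go below p = 0.5, so no test of single genes between libraries or against 0 was made and no gene is called differentially expressed.

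The following choices were made before the data were examined: the group, the main unit of each result, the thresholds, 37 gene lists with 421 entries, 9 pairs of fast and slow muscle paralogs, 38 genes for transcript shares, the rule for named genes and the main set of alternatives. Of the 421 entries, 419 matched the annotation; Norad and Rn7sl1 did not. A gene counted as detected at TPM of at least 1. Levels and shares within a library used deposited TPM, with spike-ins left out of totals. Ratios between libraries used expected counts rounded to whole numbers and scaled by the trimmed mean of M values (TMM). TPM was not used for such ratios because a change in 1 abundant RNA moves the TPM of all other genes. Against TMM scaling, deposited TPM shifts the median log2 ratio of library 2 over library 1 to 0.17, the second quantifier's TPM to 0.21 and spike-in scaling to -0.063.

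Replicates were compared over genes with mean TPM of at least 1 by Pearson's r and Spearman's rho of log2(TPM + 1), a scale that understates changes of low genes. The common biological coefficient of variation was estimated with edgeR on rounded counts with at least 1 CPM in both libraries. A chi-square test over genes asked whether the 2 libraries differed by sampling noise alone. Genes were called apart at mean TPM of at least 5, a summed count of at least 100 and an absolute log2 ratio of at least 1. Each ratio has an exact binomial (Clopper-Pearson) 95% interval from its counts. For each list, the median log2 ratio over members with mean TPM of at least 1 was placed as a percentile among 10000 random lists of the same size drawn from 50 bins of mean expression. A list was called outside the random range when its median lay outside the central 95% of those medians. Lists with under 3 such members were not described. These percentiles describe the 2 libraries only, and a ratio between 1 library and 1 library has no replicate check.

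The rule for named genes took the 20 genes with the highest mean TPM, up to 4 of the highest members of each list with up to 2 of those under TPM 1, all members of the fast and slow pairs and the Myh genes, all members of the amyloid precursor and sex-linked lists, up to 10 protein-coding or long non-coding genes apart in each direction, the 4 members with the largest absolute ratio of each list outside the central 95% of random lists, and genes whose leading transcript differed between quantifiers. It gave 252 genes, of which the text names those that head each group. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

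The dispersion step was tested on simulated data for 11577 genes with true coefficients of 0.05, 0.10 and 0.20, which were estimated at 0.0499, 0.10 and 0.196 with no changed genes. With 200 genes changed 3 times, 99.5%, 99.0% and 93.0% were recovered, and the estimates rose to 0.117, 0.143 and 0.222, so genes that differ between libraries raise the estimate. The list step was tested on 200 simulated lists of 12 among 11124 genes, of which 5% fell outside the range with no shift, 29% with a shift of 0.1 on the log2 scale and 95.5% with a shift of 0.3. Shifts of a list median near 0.1 are thus often missed by this design. The 5% with no shift follows by construction from the central 95% range. It does not show how often lists of genes that move together fall outside it.

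Alternatives covered the detection threshold, the pseudocount, the filter on low values, counts against TPM, DESeq2 size factors and dispersion trend, spike-in scaling, the second quantifier, the spike-in minimum, and each library left out. Further alternatives were added after seeing the data: totals without 7SL RNA, totals of nuclear protein-coding genes, chromosome 1 copies of mitochondrial DNA added to the mitochondrial share, and protein-coding genes alone in the random lists, the genes apart and the comparison of quantifiers. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.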

Results

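The data describe the RNA of the gastrocnemius in 1 group of 2 libraries from adult female mice of a 5xFAD and CAST cross. No label names a control tissue or genotype, so the design gives levels within this muscle and the spread between the 2 libraries. All means below are given with the SD over n = 2 libraries. Library 1 held 35594289 expected counts and library 2 held 34541905. Genes detected at TPM of at least 1 numbered 10994 in library 1 and 11216 in library 2 (11105 ± 157), and 10682 of them were detected in both. Protein-coding genes among those detected numbered 9997 in library 1 and 10181 in library 2.

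By TPM, the muscle RNA was dominated by a small set of transcripts of the signal recognition particle, the mitochondrial ribosome and the contractile apparatus. 7SL RNA, the RNA part of the signal recognition particle, held 31.2 ± 5.88% of gene TPM, and the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 stood at 58101 ± 5728 and 42209 ± 4910 TPM. Among nuclear protein-coding genes the highest was Acta1, the actin of skeletal muscle thin filaments, at 17981 ± 1441 TPM, followed by Ckm, the muscle creatine kinase that buffers ATP, at 15631 ± 1928. Tnnt3, the fast-fibre troponin T, reached 15131 ± 1519, Aldoa, a glycolytic aldolase, 12592 ± 884, and Atp2a1, the calcium pump of the fast-fibre sarcoplasmic reticulum, 12289 ± 985. The 10 most abundant genes held 53.3% of TPM in library 1 and 47.6% in library 2, and the 10 most abundant nuclear protein-coding genes held 28.8% and 29.3% of nuclear protein-coding TPM. Acta1 lies on chromosome 8 at 123891769 to 123894751, Ckm on chromosome 7 at 19404776 to 19422841 and Aldoa on chromosome 7 at 126795234 to 126800751 (mm10).

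7SL RNA was counted at a pair of identical copies, Rn7s1 (chromosome 12, 69159295 to 69159594) and Rn7s2 (chromosome 12, 69361182 to 69361481), each at 154748 ± 29323 TPM. Their reads cannot be told apart, and only their sum has meaning. The sum was 35.4% of TPM in library 1 and 27.0% in library 2. Of expected counts, which are not corrected for length, it was 6.02% and 4.10%, against 14.8% and 15.4% for the 14 fast contractile genes. Rn7sk, the small nuclear RNA that regulates RNA polymerase II elongation, stood at 14094 ± 1176 TPM. Small nuclear RNAs held 1.42% of TPM in library 1 and 0.925% in library 2, and small nucleolar RNAs 0.623% and 0.482%. Of expected counts, small nuclear RNAs held 0.0898% and 0.0527%, and small nucleolar RNAs 0.0403% and 0.0263%.

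Mitochondrially encoded messenger RNAs, which code for subunits of the respiratory chain, held 6.14 ± 0.791% of TPM. In the first quantifier mt-Co1, of cytochrome oxidase, led them at 13251 ± 1555 TPM, followed by mt-Cytb at 7967 ± 1064 and mt-Nd1 at 7106 ± 861. The second quantifier gave another order, with mt-Atp6 at 11762 and 15642 TPM beside mt-Co1 at 12340 and 14878. A further 4.43 ± 0.515% of TPM was assigned to 4 pseudogenes on chromosome 1 that are copies of mitochondrial DNA, among them Gm28661 (24614885 to 24615565) at 14363 ± 1770 TPM. These genes share reads with the mitochondrial chromosome, so both values are uncertain, and the share was 10.6 ± 1.31% with the copies added. The 16 nuclear-encoded respiratory chain genes were all above TPM 1, and the highest were Atp5b at 1311 ± 95.2 and Cox8b at 774 ± 67.8.

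**Figure D1:**
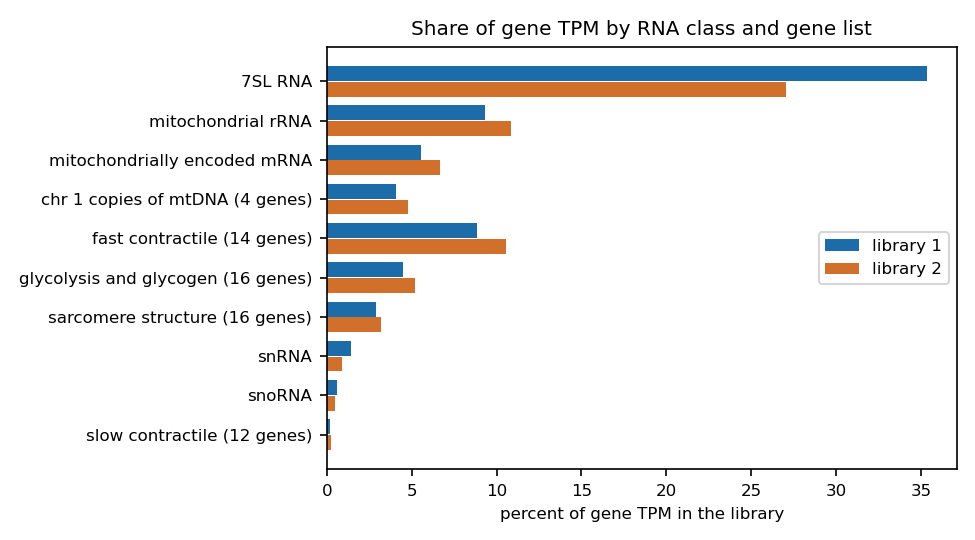
Share of gene TPM in percent (horizontal axis) held by 10 RNA classes and gene lists, with 1 bar for each library. 7SL RNA takes 35.4% in library 1 and 27.0% in library 2, and the 14 fast contractile genes take 8.86% and 10.6%.

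The contractile transcripts were those of fast glycolytic fibres. Myh4, the myosin heavy chain of type 2B fibres (chromosome 11, 67238029 to 67260446), held 86.5 ± 0.364% of the summed TPM of the adult myosin heavy chains, at 11485 ± 1204 TPM. Myh1, of type 2X fibres, held 7.35 ± 0.324%, Myh2, of type 2A fibres, 4.10 ± 0.267%, and Myh7, of slow type 1 fibres (chromosome 14, 54970684 to 54994626), 2.09 ± 0.307%. The gaps between these shares were several times their SD in each case. Each fast paralog exceeded its slow partner in both libraries in all 9 pairs, with a median log2 ratio of 4.90 ± 0.095.

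Casq1 over Casq2, the calcium-binding calsequestrins of fast and slow fibres, had a ratio of 6.53 ± 0.40 on the log2 scale. Tnni2 over Tnni1, the fast and slow troponin I genes, reached 6.16 ± 0.15, Tnnt3 over Tnnt1 reached 6.11 ± 0.17, and Atp2a1 over Atp2a2, the fast and slow calcium pumps, 6.04 ± 0.18. The smallest were Actn3 over Actn2, the alpha-actinins of the Z-disc, at 3.58 ± 0.011 and Mybpc2 over Mybpc1, the myosin-binding proteins C, at 2.62 ± 0.054. The 14 fast contractile genes held 9.72 ± 1.21% of all gene TPM and 23.0 ± 0.706% of nuclear protein-coding TPM, while the 12 slow contractile genes held 0.241 ± 0.0436% of gene TPM. The gene TPM total includes 7SL RNA and the nuclear protein-coding total does not. Developmental myosins were low beside the adult genes: Myh8, the perinatal form, stood at 69.0 ± 6.91 TPM and Myh3, the embryonic form, at 3.77 ± 0.120. Sln, which codes for an inhibitor of the calcium pump, was below TPM 1 in both libraries.

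**Figure D2:**
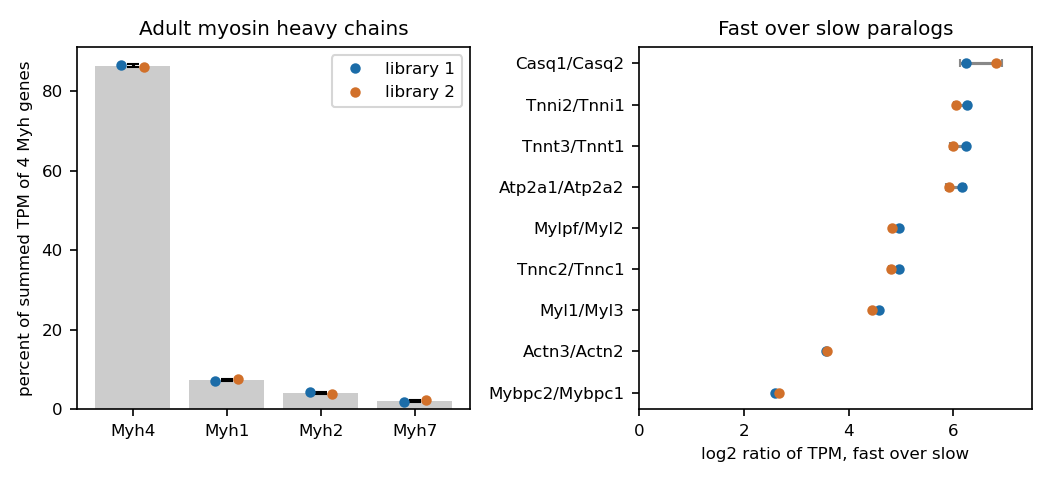
Left, percent of the summed TPM of the 4 adult myosin heavy chain genes, with bars for the mean of 2 libraries, error bars for the SD and points for single libraries; right, log2 ratio of fast over slow paralog TPM for 9 pairs, with points for libraries and grey bars for the mean ± SD. Myh4 holds 86.5% and all 9 ratios lie above 0, from 2.62 to 6.53.

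Glycolytic genes were far more abundant than those of fatty acid oxidation. All 16 members of the glycolysis and glycogen list were above TPM 1 and together held 4.85 ± 0.515% of gene TPM. They include Ckm at 15631 ± 1928 TPM and Ak1 at 632 ± 126, which are kinases of phosphate transfer and not of glycolysis, beside Gapdh at 4870 ± 386 and Pygm, the muscle glycogen phosphorylase, at 3628 ± 205. The 14 genes of fatty acid uptake and oxidation held 0.133 ± 0.00321%, led by Fabp3, a fatty-acid-binding protein, at 215 ± 6.10 TPM and Hadhb, of the trifunctional protein of beta-oxidation, at 141 ± 8.15. Among sarcomere genes, Neb (nebulin) stood at 2667 ± 310 TPM, Ttn (titin) at 2044 ± 124 and Tcap, which caps titin at the Z-disc, at 1988 ± 99.1. Ryr1, the calcium release channel of the sarcoplasmic reticulum, led the 14 excitation-contraction coupling genes at 752 ± 89.0. Mef2c, a myogenic transcription factor, stood at 184 ± 35.6 TPM, Prkaa2, a catalytic subunit of AMP-activated kinase, at 57.9 ± 9.37, and Myf6 at 47.8 ± 3.29.

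Markers of cell types other than fibres were present at low levels. Endothelial genes were all 11 above TPM 1, led by Egfl7 at 12.4 ± 2.16 and Pecam1 at 10.4 ± 0.537. Fibroblast genes were also all 11 above TPM 1, with Gsn at 221 ± 6.12 and Dcn (decorin) at 110 ± 5.09. Adipocyte markers included Car3 at 551 ± 122 TPM, which muscle fibres also express, Plin4, a lipid droplet coat protein, at 110 ± 9.29 and Cfd (adipsin) at 92.6 ± 5.00. Smooth muscle and pericyte markers included Abcc9 at 50.2 ± 5.38 and Rgs5 at 49.0 ± 3.07. Acta2 and Tagln of the same list stood at 14.1 ± 0.962 and 13.3 ± 1.97, and Cnn1 was below TPM 1 in both libraries. How much of any marker came from fibres was not tested. The tendon genes Fmod and Thbs4 stood at 30.2 ± 1.41 and 24.5 ± 0.665. The haemoglobin genes Hbb-bs and Hba-a1 stood at 87.6 ± 0.226 and 76.7 ± 0.530.

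Many markers of immune, nerve and skin cells were below TPM 1, though Lyz2 and Mbp were as high as the leading endothelial genes. Lyz2, the lysozyme of macrophages, was the highest macrophage marker at 13.6 ± 0.856 TPM, and Csf1r, the receptor that macrophages need for survival, stood at 3.69 ± 0.0707. The Schwann cell gene Mbp, of the myelin sheath, stood at 12.4 ± 0.955, and 6 of 12 members were below TPM 1. All 10 lymphocyte and neutrophil markers were below TPM 1, with Ncr1 and S100a9 at 0 counts in both libraries. Of the neuron list, whose motor neurons have their cell bodies in the spinal cord, 11 of 12 genes were below TPM 1 in both libraries, and Stmn2 stood at 1.05 and 1.42 TPM. Satellite cell markers included Itga7, which fibres also express, at 27.2 ± 2.10 TPM and Pax7, the marker of quiescent muscle stem cells, at 0.39 ± 0.269. Of the skin list 6 of 8 genes were below TPM 1 in both libraries, with the keratinocyte gene Krt10 at 1.33 and 0.76 and Trp63 the highest at 5.54 ± 0.127. Proliferation genes were below TPM 1 in 6 of 7 cases, and Pcna, of DNA replication and repair, stood at 8.52 ± 0.849. Interferon response genes were below TPM 1 in 8 of 11 cases, with Ifi27 the highest at 30.1 ± 2.99. These are levels in bulk tissue and give no share of cells.

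**Figure D3:**
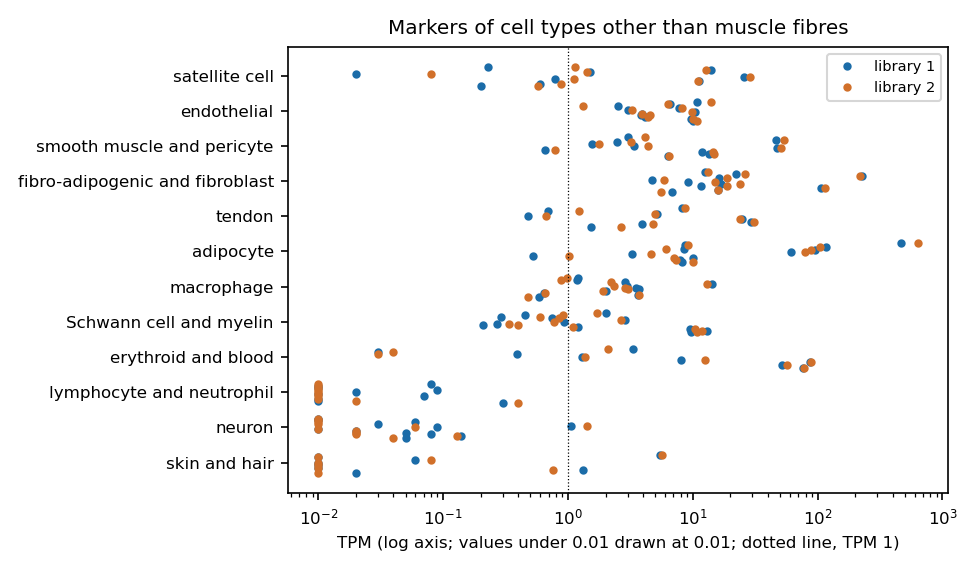
TPM on a log axis (horizontal) of the members of 12 marker lists for cell types other than muscle fibres, with 1 point per gene and library and values under 0.01 drawn at 0.01. All 10 lymphocyte and neutrophil genes and 11 of 12 neuron genes lie below the dotted line at TPM 1, while all 11 endothelial and all 11 fibroblast genes lie above it.

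The genes that produce and process the amyloid precursor protein were read because the line carries transgenes of this pathway. The mouse App gene (chromosome 16, 84949685 to 85173766) stood at 25.6 ± 1.48 TPM, and its homologue Aplp2 at 43.6 ± 7.27. Of the gamma-secretase genes, Psenen stood at 56.2 ± 0.728 TPM, Aph1a at 17.7 ± 1.46, Ncstn at 11.1 ± 0.488 and Psen2 at 2.97 ± 0.0566. The beta-secretase gene Bace1 stood at 14.7 ± 5.86 and the alpha-secretase gene Adam10 at 6.17 ± 0.608. Bace2, a relative of Bace1, stood at 1.63 TPM in library 1 and 0.46 in library 2, from 41 and 31 counts. The second quantifier gave Bace2 0.269 and 0.372 TPM, so its level and direction are not settled. Ide and Mme, proteases that degrade amyloid beta, stood at 42.3 ± 4.11 and 1.72 ± 0.106, Apoe at 25.3 ± 0.0212, Mapt (tau) at 28.9 ± 1.56, Thy1 at 2.33 ± 0.346 and Aplp1 at 0.405 ± 0.106. The list as a whole had a median log2 ratio between libraries of 0.033, at percentile 74.7 of random lists. The transgenes are human sequences outside the annotation used, so their expression was not measured. Whether some of their reads were assigned to the mouse entries was not tested.

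Both libraries are labelled female, and in the first quantifier both held Xist with next to no RNA of 4 genes of the Y chromosome. Xist, the RNA that coats the inactive X chromosome, stood at 10.5 ± 0.919 TPM. The 4 Y-linked genes, Ddx3y, Uty, Kdm5d and Eif2s3y, were at or below 0.02 TPM in each library, and Kdm5d had 0 counts in both, which allows up to 0.0847 and 0.0873 CPM. The second quantifier gave Uty 0.387 TPM in library 1 and 0.370 in library 2, and Kdm5d 0.0971 and 0.0580. It also gave the Y-chromosome gene Gm47283 21.7 and 8.68 TPM, where the first quantifier gave 0. Tsix, the antisense partner of Xist, was at 0.02 TPM in library 1 and 0 in library 2.

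The 2 libraries were close over most genes but were not copies of 1 library. Across 11124 genes, r was 0.983 and rho 0.976 on log2(TPM + 1), where genes are not independent replicates. The median absolute log2 ratio was 0.12, with 94.4% of genes within 1.5 times and 98.1% within 2 times of each other. The common biological coefficient of variation was 0.0941 over 11577 genes, and the chi-square over genes was 18.6 per degree of freedom (15959 degrees of freedom), far above sampling noise. Abundant genes weigh most in this sum. 7SL RNA enters it at both of its identical copies, each with 1067065 counts in library 1 and 704809 in library 2. The value of 18.6 is therefore not typical of single genes. The 33 spike-ins with at least 100 reads had an SD of log2 ratios of 0.14, equal to that expected from counting, against 0.27 for genes of the same counts.

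Few genes stood apart between libraries, and most of those were higher in library 1. Fos, an immediate early transcription factor (chromosome 12, 85473890 to 85477273), had 519 counts in library 1 and 95 in library 2, a log2 ratio of -2.42 (95% counting interval -2.75 to -2.10). Depp1, a target of FoxO factors, had a ratio of -2.08, Thbs1, the matrix protein thrombospondin, -1.62, and Cebpd, an acute-phase transcription factor, -1.42. In the other direction, Nmrk2, a nicotinamide riboside kinase of muscle (chromosome 10, 81198170 to 81202051), had a ratio of 1.68 (1.49 to 1.87), and Ky, a Z-disc-associated protease (chromosome 9, 102505750 to 102546239), 1.26 (1.21 to 1.32). In all, 34 of 6685 genes were apart, 26 higher in library 1 and 8 higher in library 2. On deposited TPM, which carries the shift from 7SL RNA, 31 genes were apart, 14 higher in library 1 and 17 higher in library 2, and 21 of them were among the 34.

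Of the 34 genes apart, 22 were protein-coding, 17 higher in library 1 and 5 higher in library 2. Those higher in library 1 included Chrna9, a nicotinic acetylcholine receptor subunit, at -1.57, Ankrd1, a titin-binding stress protein, at -1.25, the metallothioneins Mt1 and Mt2 at -1.14 and -1.13, and Gpx3, a secreted glutathione peroxidase, at -1.13. Gm21887, at the end of the X chromosome, had a ratio of -1.75. The others higher in library 2 were the phosphatase gene Dupd1 at 1.19, Tnfaip2 at 1.04 and the potassium channel subunit Kcng4 at 1.02. Most of the remaining 12 were pseudogenes and small RNAs, which share reads with other copies. These differences have no replicate check.

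**Figure D4:**
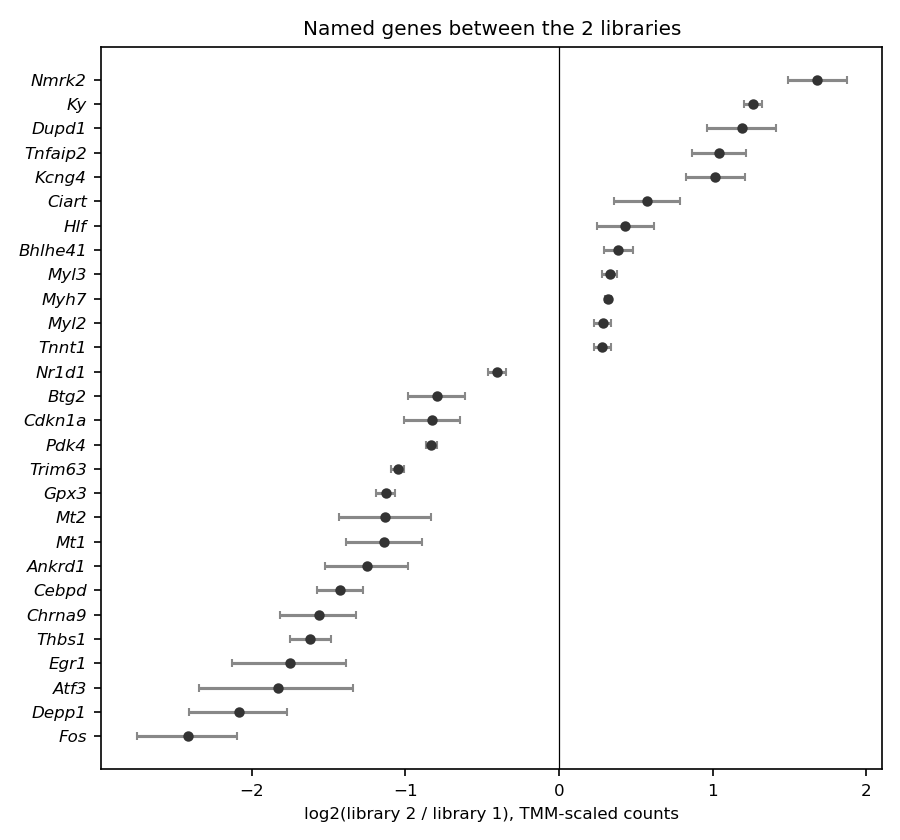
Log2 ratio of TMM-scaled counts, library 2 over library 1 (horizontal axis), for 28 named genes, with exact binomial 95% counting intervals as bars. Fos lies at -2.42 and Nmrk2 at 1.68, and the intervals cover counting error only.

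Of the 37 gene lists 32 could be described, and 15 had a median ratio outside the central 95% of random lists, 8 higher in library 1 and 7 higher in library 2. The furthest was the glucocorticoid and fasting response, with a median of -0.74, below all 10000 random lists and with 9 of 10 members higher in library 1. Pdk4, which blocks glucose oxidation by inhibiting pyruvate dehydrogenase, had 230 TPM in library 1 and 138 in library 2, a log2 ratio of -0.83. Other members moved far less: Tsc22d3 had 7365 and 6749 counts, a ratio of -0.093, and Klf9 7974 and 6919, a ratio of -0.17. Whether a glucocorticoid signal differed between the libraries was not tested. The atrophy and denervation list had a median of -0.54, also below all random lists, with 10 of 12 members higher in library 1. Its ubiquitin ligase genes Trim63 (chromosome 4, 134315120 to 134329629) and Fbxo32, which mark muscle protein breakdown, had ratios of -1.05 and -0.71, and the cell cycle inhibitor Cdkn1a -0.83. The lists share Mt1, Mt2 and Fbxo32, so they are not separate evidence.

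The immediate early list had a median of -0.49, below all random lists, with 8 of 10 members higher in library 1, among them Atf3 at -1.83, Egr1 at -1.75, Btg2 at -0.80 and Jun at -0.66 beside Fos. Macrophage markers had a median of -0.47 (percentile 0.02), and all 9 measured members were lower in library 2, with Ctss at -0.60 and the complement gene C1qc at -0.51. Schwann cell and myelin genes had a median of -0.31 (percentile 0.25), with Drp2 at -0.57 and Mbp at -0.31. Structural non-coding RNAs had a median of -0.41 (percentile 1.07), with Rpph1, the RNA of ribonuclease P, at -0.57 and Rmrp at -0.46. Long non-coding RNAs had a median of -0.24 (percentile 0.69), with Neat1, the scaffold of paraspeckles, at -0.50. The genes of fatty acid uptake and oxidation had a median of -0.12 (percentile 0.76), which was 0.025 on deposited TPM and 0.026 on the second quantifier's TPM before the shift of all genes was removed, and the largest single ratio was that of Ucp3, a mitochondrial uncoupling protein, at -0.51.

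Among lists higher in library 2, the slow contractile genes had a median of 0.25, at percentile 100, with 8 of 11 members higher, among them Myl3 at 0.33, Myh7 at 0.32, Tnnt1 at 0.28 and Myl2 at 0.28. The circadian clock list had a median of 0.14 (percentile 99.6), with Ciart at 0.57, Hlf at 0.43, Bhlhe41 at 0.39 and Nr1d1 at -0.40. Neuromuscular junction genes had a median of 0.26 (percentile 99.97), with 7 of 11 members higher, Ufsp1 at 0.65 and the acetylcholinesterase gene Ache at 0.44, but the list was inside the random range on deposited TPM (percentile 44.1) and on the second quantifier's TPM (percentile 82). Smaller medians outside the range were those of mitochondrially encoded mRNAs at 0.097 (percentile 98.5), of which mt-Nd6 and mt-Co2 were at -0.16 and -0.15 but above 0 on deposited TPM, and mt-Co2 also on the second quantifier's counts. Fast contractile genes had a median of 0.085 (percentile 98.4), glycolysis and glycogen genes 0.070 (97.8) and excitation-contraction coupling genes 0.063 (97.6), the last at -0.00096 under spike-in scaling. None of these 4 lists stayed outside the range when random lists were drawn from protein-coding genes alone, nor on the second quantifier's TPM.

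The other 17 described lists lay inside the random range. Medians were -0.12 for the developmental myosin and the endothelial lists, -0.11 for ribosomal proteins, -0.18 for satellite cells, -0.098 for tendon genes, -0.099 for blood genes, -0.073 for adipocyte genes and -0.027 for sarcomere genes. Smooth muscle genes were at -0.0085, myogenic regulator genes at -0.0064, heat shock genes at -0.0037, interferon and amyloid precursor genes at 0.033, fibroblast genes at 0.035, nuclear-encoded respiratory chain genes at 0.047, histone genes at 0.049 and extracellular matrix genes at 0.059. The lymphocyte, neuron, skin, proliferation and sex-linked lists had under 3 members at TPM of at least 1 and were not described between libraries. With random lists of protein-coding genes alone, the endothelial list fell to percentile 2.03 and the ribosomal list to 0.78, which put both outside the range. The adipocyte list was outside it, lower in library 2, on deposited TPM (percentile 0.54) and on the second quantifier's TPM (percentile 0.03), as was the ribosomal list on the latter (percentile 2.14).

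**Figure D5:**
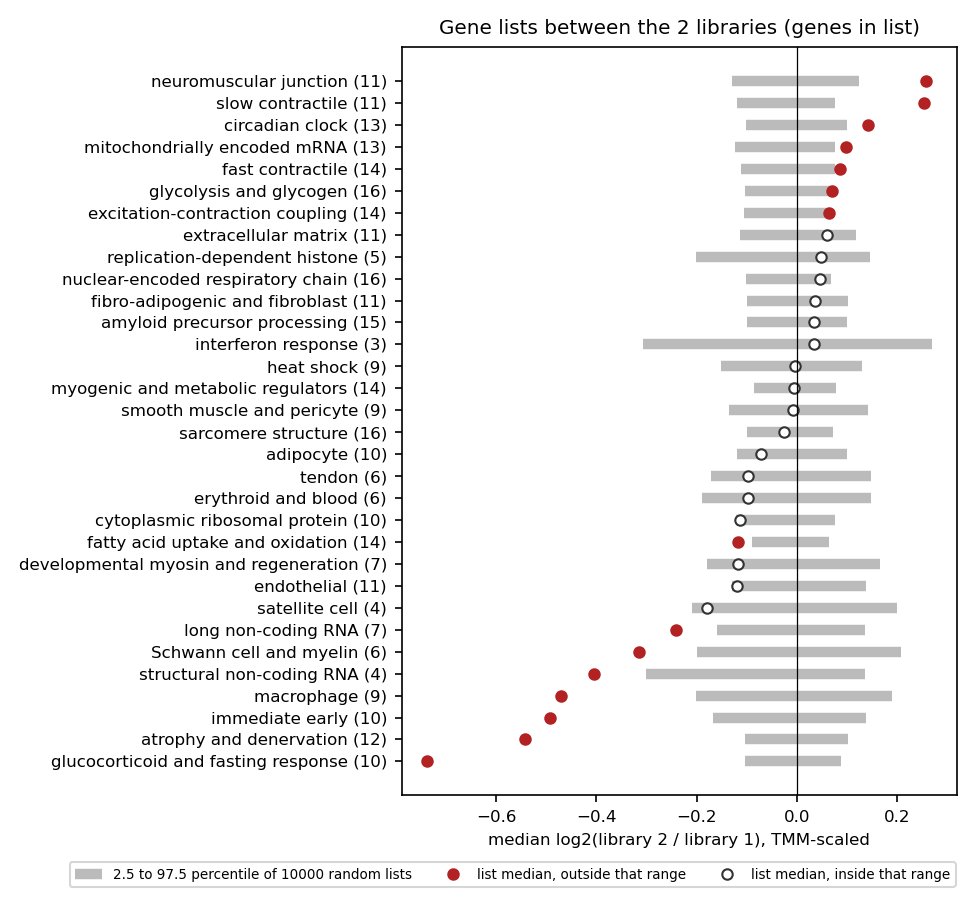
Median log2 ratio of TMM-scaled counts, library 2 over library 1 (horizontal axis), for 32 gene lists with the number of measured genes in brackets; grey bars are the central 95% of 10000 random lists, filled points lie outside it and open points inside. The glucocorticoid and fasting list is lowest at -0.74 and the neuromuscular junction list highest at 0.26, though the latter lies inside the range on deposited TPM.

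The quantifiers gave close values for most protein-coding genes and far different ones for many small nuclear RNAs, small nucleolar RNAs and pseudogenes. The most abundant short RNAs were close. 7SL RNA held 38.8% and 28.8% of TPM in the second quantifier, against 35.4% and 27.0% in the first. Rn7sk stood at 18756 and 16564 TPM in the second and 14926 and 13262 in the first. Across 11590 genes r was 0.891 in library 1 and 0.896 in library 2, and across 10301 protein-coding genes 0.982 and 0.981, where genes are not independent replicates. In both libraries 532 genes were over 2 times apart, of which 315 were higher in the first quantifier, and among 10295 protein-coding genes 86 were. mt-Atp8, a subunit of the mitochondrial ATP synthase whose reading frame overlaps mt-Atp6, was at 3994 and 4925 TPM in the first quantifier and at 6.66 and 10.7 in the second, so its level is not settled here, and it was chosen after its values were seen. All 23 small nuclear RNA genes tested between libraries were below TPM 1 in the second quantifier.

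Leading transcripts were read for 37 muscle genes above TPM 10, and both quantifiers named the same one for 31 of them. Atp2a1-201 held 99.9 ± 0.0160% of Atp2a1 TPM and Ryr1-202 held 95.4 ± 0.199% of Ryr1 TPM, and in the second quantifier Ryr1-202 held 96.3%. Tpm1-205, of tropomyosin, held 96.9 ± 0.152% in the first quantifier and 73.9 ± 0.0540% in the second. App-203 held 59.4 ± 0.930% of App TPM. The quantifiers named different leading transcripts for Tnnt1, Neb, Mbnl1, Fhl1, Myl1 and Eef1d, whose transcript shares are therefore not firm. For Myl1, which codes for alkali light chains of fast myosin, the first gave Myl1-202 75.6 ± 0.0586% and the second gave Myl1-207 49.4 ± 2.46%.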

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

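All tests in this part were chosen only after the result was seen, except the one on lipogenic genes, whose expected outcome was written down before those genes were looked at. The 2 libraries form 1 group, so the design gives no biological factor to set against technical ones.

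Sequence of phiX, the phage often added to sequencing runs as a control, was found in both libraries although it is no part of the muscle. It held 220 expected counts in library 1 and 255 in library 2, above the 3 counts that a count of 0 allows, which is 6.18 and 7.38 CPM. The second quantifier assigned it 248 and 283 estimated counts.

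Small structured RNAs were lower in library 2, with a median log2 ratio of -0.79 over 23 small nuclear RNA genes, all lower, and of -0.59 over 29 small nucleolar RNA genes, 27 of them lower. The 23 genes include near-identical copies with 12 distinct pairs of counts, and all are below TPM 1 in the second quantifier. A scaling difference between libraries would move all genes alike, and is argued against, since the small nuclear RNA median lay at -0.79 relative to that of protein-coding genes. TMM scaling had already put the protein-coding median at 0.0045, so this value restates the pattern and is no separate evidence. A lower share of nuclear RNA stays open for small nuclear and nucleolar RNAs, because 5 nuclear long non-coding RNAs (Malat1, Neat1, Meg3, Kcnq1ot1 and Xist, of which Kcnq1ot1 was chosen after its value was seen) had a median of -0.24, between the bounds set for and against it. Loss of short RNA during library preparation also stays open, because the ratio rose only weakly with gene length over 66 small RNA genes (Spearman's rho 0.14, genes not being independent replicates), though 29 protein-coding genes under 400 nt go against it with a median of 0.0024, and no biological explanation was tested.

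Glucocorticoid, fasting and atrophy genes were higher in library 1, with list medians of -0.74 and -0.54. The adipocyte list median was -0.073, but -0.19 on deposited TPM and -0.29 on the second quantifier's TPM relative to all genes. More adipocyte RNA in library 1 is argued against as the whole source for glucocorticoid and fasting genes. The adipocyte median lay at least 0.42 above theirs, against an SD of 0.32 across adipocyte genes. A smaller part from adipocytes stays open, since the list holds Car3, which fibres also express and which was higher in library 2. For atrophy genes this explanation stays open, where the gap was 0.27 on the second quantifier's TPM. Handling stress stays open, since the immediate early list goes with it at a median of -0.49, below all random lists, while the heat shock list lay at percentile 49.3 with members in both directions, which decides nothing. A candidate explanation is that the tissue of library 2 was taken closer to a meal: of 10 lipogenic genes, which insulin and feeding raise, the 8 that the muscle expressed at TPM of at least 1 had a median of 0.14 at percentile 97.7, with 7 higher in library 2. That percentile was 90.7 on deposited TPM and 84.0 on the second quantifier's TPM, so the hypothesis rests on a narrow margin in 2 libraries.

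Macrophage markers were lower in library 2 in all 9 measured members, with a list median of -0.47. Counting error alone is argued against, since the counts summed over all 11 list members, 1943 and 1465, gave a log2 ratio of -0.37 with a 95% counting interval of -0.47 to -0.28. A lower share of all cells other than fibres in library 2 is argued against too, since the fibroblast list, the highest of the endothelial, smooth muscle and fibroblast lists, had a median of 0.035, although other lists fell as well, with medians of -0.31 for Schwann cell and myelin, -0.12 for endothelial and -0.073 for adipocyte genes, so a lower share of some of these cells stays open. A difference in macrophage content between the tissue pieces may remain, and no biological explanation was tested.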

How the results depend on the processing

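Alternatives on 7SL RNA totals, nuclear protein-coding totals, chromosome 1 copies and protein-coding genes alone were chosen only after the result was seen. Of the main results, 27 values stayed within the spread or count limit and 22 moved. Of values for single genes and lists, 849 stayed, 276 moved and 3 reversed. These tallies include means with 1 library left out, which stay within the SD by construction, so they do not measure stability. Genes at 0 TPM in both libraries have an SD of 0 and were tallied as moved without any change. Of the cause, only what an alternative's own construction shows is known, and otherwise the cause was not tested. No paired analysis was possible because the series has 1 group.

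By construction, other thresholds or totals moved genes detected to 16693 at TPM 0.1 and 6750 at TPM 5, genes apart from 34 to 75 at mean TPM of at least 1 and to 22 for protein-coding genes alone, spike-in SD to 0.25 at 20 reads, the mitochondrial share to 10.6% with the chromosome 1 copies and 8.90% without 7SL RNA, and the fast contractile share to 11.6% without mitochondrial genes, 14.1% without 7SL RNA and 23.0% of nuclear protein-coding genes. Counts without length correction gave a Myh7 share of 1.63% and a mitochondrial share of 4.49%. The replicate r was 0.965 with a pseudocount of 0.1, 0.994 without a filter and 0.993 on CPM, and the coefficient of variation 0.107 without a filter and 0.138 from the DESeq2 trend. The second quantifier gave a median fast over slow ratio of 5.38 and a mitochondrial share of 7.61%. The first quantifier's leading transcripts held a median of 59.3 ± 0.902% of their genes in the first quantifier and 57.9% in the second, whose own leading transcripts held a median of 60.3%. The quantifiers' r was 0.752 at TPM of at least 10 and 0.981 for protein-coding genes.

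The 3 reversed values were list medians near 0: excitation-contraction coupling at -0.00096 under spike-in scaling, and fatty acid genes at 0.025 on deposited TPM and 0.026 on the second quantifier's TPM, which follow from shifts of all genes of -0.063, 0.17 and 0.21. Single genes with ratios under 1 in size were not counted as reversed, but mt-Nd6 crossed 0 to 0.014 on deposited TPM, and mt-Co2 to 0.030 on deposited TPM and 0.059 on the second quantifier's counts. Lists outside the range numbered 13 on deposited TPM and 12 on the second quantifier's TPM. Under spike-in scaling they numbered 15 by construction, since it shifts each list and its random lists by the same constant, so this number says nothing on stability. Genes apart numbered 34 under DESeq2 size factors, 36 under spike-in scaling and 37 on the second quantifier's counts, of which 34, 32 and 23 were among the 34 of the main setting.

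Leaving out each library in turn gave 10994 to 11216 genes detected, a Myh7 share of 1.87 to 2.31%, a fast over slow median of 4.84 to 4.97, a mitochondrial share of 5.58 to 6.70%, a fast contractile share of 8.86 to 10.6%, a quantifier r of 0.891 to 0.896 and a leading transcript share of 58.7 to 59.98%. With 2 libraries this moves a mean by 0.707 SD by construction, so it says nothing on stability, and it gives no value for ratios between libraries, replicate r, the coefficient of variation or spike-ins. Depth limits low genes, since 3 counts are 0.0847 to 0.0873 CPM.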

Other observations

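All genes in this part were chosen after their values were seen. Ighm, the constant region gene of the immunoglobulin M heavy chain (chromosome 12, 113418558 to 113422730), was the gene furthest higher in library 2 among the 34 genes apart, with 784 counts in library 1 and 3566 in library 2, a log2 ratio of 2.22 (95% counting interval 2.11 to 2.33) and 16.3 and 86.2 TPM. The second quantifier gave 13.8 and 75.3 TPM. Of the other immunoglobulin constant genes, Ighg2c had 31 and 57 counts and Igha 17 and 4. The B cell markers Cd79a and Ms4a1 had at most 3 counts in either library, so transcripts of immunoglobulin M were present without a matching level of B cell surface markers, and no explanation was tested. Foxo1, a transcription factor that raises Trim63 and Fbxo32 in fasting muscle, had 3533 and 1690 counts, a ratio of -1.03 (-1.12 to -0.95).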
